A study of Homo sapiens with 2 samples.

How the data were processed

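Poly(A)-selected RNA of 1 MCF7-Ctrl and 1 MCF7-TWIST1 sample was sequenced as strand-specific libraries in which dUTP marked the second strand, with ERCC spike-in RNA added, per the labels' protocols. STAR, DESeq2 and the genome build hg38 are named per the submitters' processing notes, without versions or settings. The counting step, its strand setting, any filter and the dispersion estimate are not given in the sources used here. Groups were taken from the sample titles.

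The first deposited table gives, per gene, the authors' log2 fold change. The p-value and adjusted p-value of each gene in it are also the authors', per the file headers. The direction, MCF7-TWIST1 over MCF7-Ctrl, is taken from the header of the second deposited table. That second table gives the authors' linear fold (a ratio) for 5109 higher and 6050 lower genes, and each of its folds equals the first table's within 0.0001 on the log2 scale. Its header describes the lower genes as those under 0.067, per the file headers, while its values reach 0.666. Neither table holds a count, a level per library or an ERCC row, so the depth of each library is unknown, and spike-in scaling and mean expression were not analysed here. The relative size factor of the libraries was read only from folds that many genes share, for a test in the closing section. No intervals for counting error were computed.

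An adjusted p is given for 5945 of the 32412 genes in the authors' deposited table. These 5945 took the place of the planned filter on low values, because mean expression was not used here. The values are the authors' folds and p-values and not counts, so the planned count-based folds, tests and Poisson intervals were replaced by counts of genes at or past a 2-fold difference. With 1 library per group the authors' p-values describe a difference between 2 libraries under the dispersion their tool assumed, and measure no spread between cultures.

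All 32412 gene identifiers, versions included, match GENCODE release 29 on GRCh38, which gave coordinates and gene types. Symbols are the table's own, and 26 of them differ from that annotation. Where several rows share a symbol, which 86 symbols do, the row with an adjusted p and a protein-coding type was used. Reads of overlapping genes and near-identical copies may have been split or shared by the authors' counting, and such genes are uncertain.

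The gene lists, 37 in all, were fixed from background knowledge before the data were examined. For each list with at least 5 members with an adjusted p, the median log2 fold was placed among 10000 random lists of the same size drawn from the 5945 genes. Percentiles below 2.5 or above 97.5 are called outside. The planned matching on mean expression was not possible. The percentile describes these 2 libraries and is no test of the conditions. For counts "adjusted over the list alone", the authors' p-values of all members in the table, with or without an adjusted p, were adjusted by the Benjamini-Hochberg method within the list.

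The implied error of a fold is the absolute log2 fold divided by the normal deviate of the authors' two-sided p. Genes on the outer curve are those at log2 folds of at least 2 in size whose implied error is at least 0.94 of the highest at neighbouring folds (within 1.1 log2). The ratios left a gap between 0.900 and 0.992. The neighbourhood was redefined once, after a first version miscalled simulated genes. Reading the curve as genes without a read in 1 library is an inference from the values.

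Named genes follow a rule written before the data were examined. It takes TWIST1, the 12 highest and 12 lowest log2 folds among genes with an ordinary symbol, 14 genes fixed by name, and the most extreme members of each list described. The rule also asked for an adjusted p under 0.05 and a minimum of mean expression. No gene met the first and the second could not be read, so genes with any adjusted p were used. Genes of 2 chromosome regions and those opening the other observations fall outside the rule and were chosen after their values were seen.

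For location, genes with an adjusted p on chromosomes 1 to 22 and X were cut into windows of 50 neighbours, and the SD of the window medians was compared with 1000 shuffles of gene positions. Alternatives were other fold thresholds, no filter, protein-coding genes, the mean, other random lists, and lists without shared members. Re-centring, leaving out the outer curve and leaving out 2 regions were added after the data were seen.

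The list step was tested on simulated data over 5939 genes. Lists of 25 genes shifted by 0, 0.5, 1 and 2 log2 were called outside in 7%, 54%, 97.5% and 100% of draws. Lists of 10 genes were called in 5%, 24%, 71.5% and 99.5%. The window step, over 5900 genes with some of the windows shifted, was called in 5% of draws at a shift of 0 and in 100% at 0.5. Those calls came from few draws, with fewer shuffles and a lower bar than were set for the data. Under an assumed model of counts, against which its definition had been adjusted, the outer curve step recovered 100% of 4084 simulated genes without a read in 1 library, and 0% of its calls were wrong. That model replaced each count of 0 by 1 fixed value, so these genes formed a separate curve by construction. The result therefore does not test the reading of the curve in the data. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.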

Results

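RNA was sequenced from 2 cell lines that the labels name as MCF7, an established human breast cancer cell line of the luminal, estrogen receptor-positive type. In the first, MCF7-TWIST1, the transcription factor TWIST1 was overexpressed; TWIST1 is a basic helix-loop-helix factor known for its part in epithelial-mesenchymal transition. The second, MCF7-Ctrl, served as the control. The labels list 1 sample per group, so no difference below has a replicate check and no p-value was computed across genes. Comparisons with random lists or shuffled positions describe these 2 libraries. Folds also followed chromosomal position, so a different origin of the MCF7-TWIST1 cells stays open, as the closing section describes. The deposited tables hold the authors' fold and p for each of 32412 genes and no level per library, so the depth of either library is unknown. Every value given for a single gene comes from the authors' deposited table, as a log2 fold of MCF7-TWIST1 over MCF7-Ctrl in which a positive value is higher in MCF7-TWIST1.

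The comparison asks which genes differ in expression between the 2 cell lines. In the authors' deposited table most measured genes of the luminal epithelial lists were lower in the MCF7-TWIST1 library, and most of the mesenchymal lists were higher. E-cadherin (CDH1), the main adhesion protein of epithelial junctions, stood at a log2 fold of -13.80, and the estrogen receptor (ESR1) at -10.02, in the authors' deposited table. The intermediate filament vimentin (VIM) stood at 10.47 and the receptor tyrosine kinase AXL at 12.64 in the same authors' deposited table. Of 5945 genes with an adjusted p, 1339 were at least 2-fold higher and 858 at least 2-fold lower in the MCF7-TWIST1 library, so that 60.9% of these differences were upward. That share was 50.2% after the folds were re-centred on their median of 0.18, and 39.9% over all 32412 genes. None of these genes had an adjusted p under 0.05 in the authors' deposited table. The lowest adjusted p was 0.0949, shared by 69 genes, and 1425 genes had an unadjusted p under 0.05 in the authors' deposited table, 629 of them higher and 796 lower, which is 4.40% of all genes. Among genes with an adjusted p these counts were 152 higher and 120 lower in the authors' deposited table.

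The error that the authors' p implies for a fold (the absolute log2 fold divided by the normal deviate of the p) had a median of 1.58 among genes with an adjusted p. The smallest absolute log2 fold with an unadjusted p under 0.05 in the authors' deposited table was 4.37. A further limit concerns 9918 genes, 30.6% of the table, whose implied errors lie on a single outer curve, as they would if 1 of the libraries had no read of the gene. Their folds are fitted values, neither measured ratios nor bounds, and 41 of them have an adjusted p. Off this curve, 383 higher and 333 lower genes had an unadjusted p under 0.05 in the authors' deposited table.

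**Figure D1:**
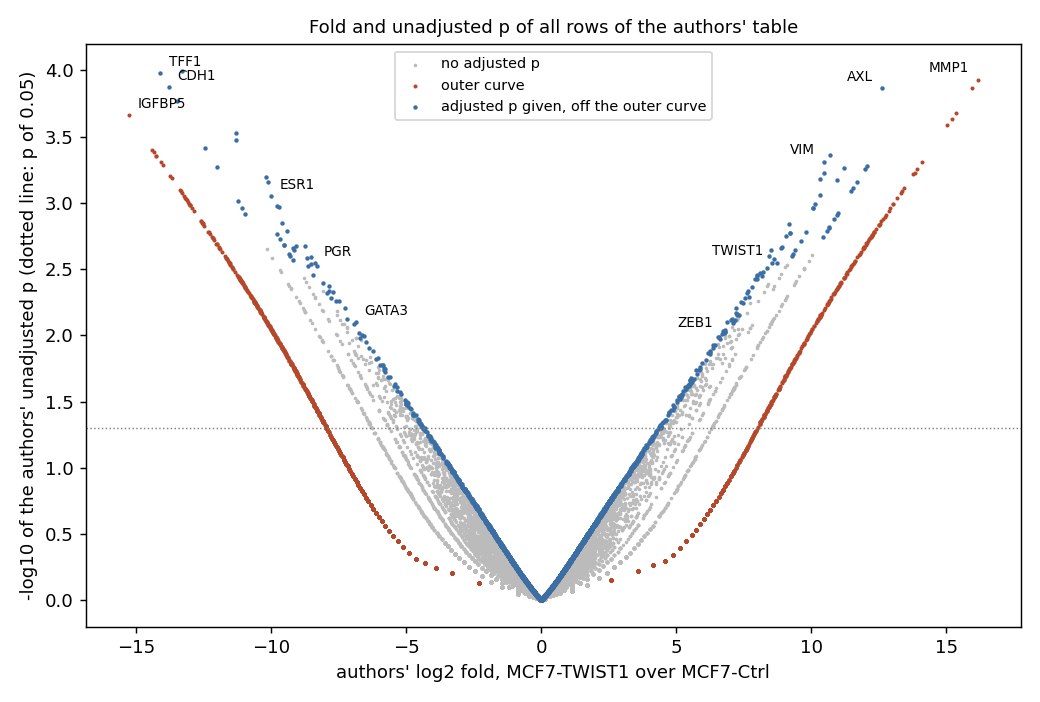
Each point is a gene of the authors' deposited table, with the log2 fold of MCF7-TWIST1 over MCF7-Ctrl on the x axis and -log10 of the unadjusted p on the y axis. Most of the 5945 genes with an adjusted p lie along the inner edge (41 lie on the outer curve), the 9918 genes of the outer curve form the outermost line on each side, and the dotted line marks a p of 0.05.

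TWIST1 (ENSG00000122691.12, chromosome 7, 19020991 to 19117672, minus strand, GRCh38) had a log2 fold of 8.57 in the authors' deposited table, a linear fold of 380. Its implied error was 2.87, its p was 0.00282 and its adjusted p was 0.151 in the authors' deposited table. It was higher in the library labelled as overexpressing it. Transcripts of the introduced and of the native gene are not told apart by these values. Among genes with an adjusted p, 54 had a higher fold than TWIST1.

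Genes of epithelial junctions and polarity were lower as a group. Of 22 members with an adjusted p, 18 were at least 2-fold lower and 2 at least 2-fold higher, and their median log2 fold of -5.72 lay below all 10000 random lists of the same size. GRHL2, an epithelial transcription factor, stood at -14.10, CDH1 at -13.80, the tight junction protein CLDN3 at -13.03 and the plakin PPL at -9.52 in the authors' deposited table. GRHL2 and CLDN3 lie on the outer curve. Counts adjusted over a list alone, here and below, cover all its members with a fold, 40 for this list. CDH1 (ENSG00000039068.18, chromosome 16, 68737225 to 68835548) had an implied error of 3.61 and a p of 0.000134 in the authors' deposited table. With the authors' p adjusted over the list alone, 19 members passed 0.05, all lower, against 0 over all genes. Luminal keratins and mucins were lower as well, with 6 of 6 members at least 2-fold lower, a median of -3.89, and 3 lower members passing 0.05 adjusted over the list alone against 0 over all genes. TFF1, a secreted trefoil peptide, stood at -14.11, AGR2 at -8.75 and keratin 8 (KRT8) at -4.30 in the authors' deposited table.

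The estrogen receptor and the transcription factors of luminal identity had a median log2 fold of -5.23, with 13 of 14 members at least 2-fold lower. ESR1 (ENSG00000091831.23, chromosome 6, 151656691 to 152129619) stood at -10.02 with an implied error of 3.01 and a p of 0.00089 in the authors' deposited table. The progesterone receptor PGR stood at -8.39, the pioneer factors GATA3 and FOXA1 at -6.87 and -5.88, and the receptor ERBB3 at -6.62 in the authors' deposited table. Genes of the estrogen response had a median of -3.21, and 22 of 26 members were at least 2-fold lower while 2 were at least 2-fold higher. TFF1, the receptor tyrosine kinase RET (-13.18, on the outer curve), GREB1 (-10.11) and the fatty acid elongase ELOVL2 (-9.42) were the most extreme in the authors' deposited table. Adjusted over the list alone, 9 members of each of these 2 lists passed 0.05, all lower, against 0 over all genes. Both medians lay below all 10000 random lists.

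Mesenchymal structure and matrix genes were higher as a group, with 14 of 18 members at least 2-fold higher, 2 at least 2-fold lower and a median log2 fold of 5.57, above all 10000 random lists. COL8A1, a short-chain collagen, stood at 13.36 on the outer curve, the matrix protein TNC at 10.95 and VIM at 10.47 in the authors' deposited table. VIM (ENSG00000026025.15, chromosome 10, 17228259 to 17237593) had an implied error of 3.0 and a p of 0.000488 in the authors' deposited table. IGFBP5, a secreted binding protein of insulin-like growth factors placed in this list, went the other way at -15.28 on the outer curve in the authors' deposited table. FN1, fibronectin, stood at 2.53 with a p of 0.179, and N-cadherin (CDH2) at -1.19 with a p of 0.792, in the authors' deposited table. Adjusted over the list alone, 11 higher members and 1 lower member passed 0.05, against 0 over all genes. The median was 1.89 when the members without an adjusted p were kept. For CDH2 the fold and p imply an error above the 1.58 that is the median among genes with an adjusted p. Its direction is therefore uncertain.

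Transcription factors of epithelial-mesenchymal transition (EMT), TWIST1 among them, had a median of 7.27 over 8 members, of which 6 were at least 2-fold higher and 1 at least 2-fold lower. ETS1 stood at 15.05 on the outer curve, HMGA2 at 8.73, FOSL1 at 7.83 and ZEB1 at 6.72 in the authors' deposited table. ZEB2 (8.44) and SNAI2 (7.74) were higher without an adjusted p, and SNAI1 stood at 0.24 with a p of 0.929, in the authors' deposited table. Adjusted over the list alone, 8 members passed 0.05, all higher, against 0 over all genes, and the median was 2.77 when members without an adjusted p were kept. Markers fixed beforehand for mesenchymal-like breast cancer lines as a class, 13 of whose 20 genes another list also holds, had a median of 8.22, with 11 of 11 members at least 2-fold higher. Among them were moesin (MSN, 15.97) and the proteoglycan core protein serglycin (SRGN, 15.20), both on the outer curve, and AXL (12.64) in the authors' deposited table. Counts adjusted over the list alone cover all 22 EMT factors and all 20 line markers with a fold, not only those with an adjusted p. Which genes have an adjusted p may depend on their level, so genes low in 1 library may be counted only when high in the other. Over all 20 mesenchymal-like line markers, those without an adjusted p kept, the median was 6.59. Adjusted over that list alone, 12 members passed 0.05, all higher, against 0 over all genes.

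**Figure D2:**
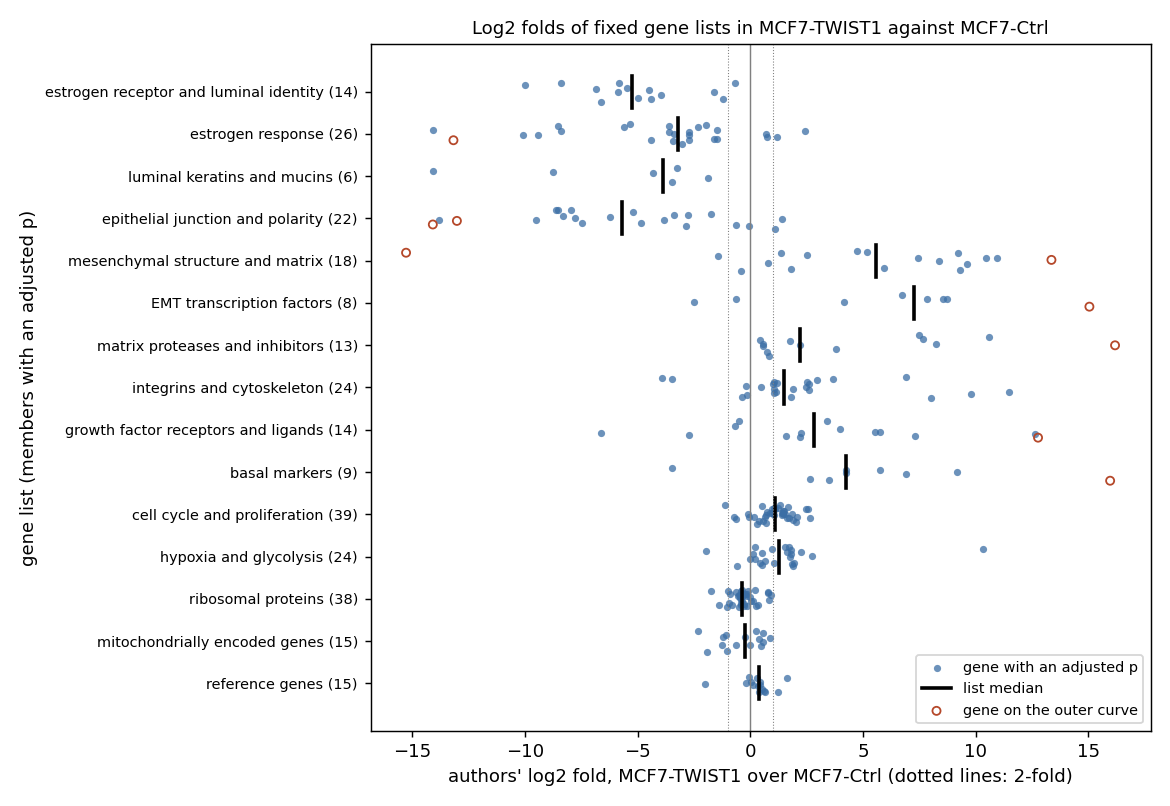
Each point is a gene with an adjusted p, placed by its log2 fold in the authors' deposited table on the x axis and by its list on the y axis, with open circles for genes on the outer curve and a black bar for the list's median. Of the 15 lists drawn, medians run from -5.72 for epithelial junction and polarity genes to 7.27 for transcription factors of epithelial-mesenchymal transition, while reference genes sit at 0.39.

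Lists of the cell surface, matrix turnover and motility were also above the random lists. Basal markers had a median of 4.25 with 8 of 9 members at least 2-fold higher and 1 at least 2-fold lower, and matrix proteases and their inhibitors a median of 2.20 with 8 of 13 higher and 0 lower. The collagenase MMP1 stood at 16.18 on the outer curve, the protease ADAMTS1 at 10.58 and urokinase (PLAU) at 8.22 in the authors' deposited table. Integrins and cytoskeleton genes had a median of 1.48, with 18 of 24 at least 2-fold higher and 2 lower, led by filamin C (FLNC, 11.48) and the GTPase RAC2 (9.81) in the authors' deposited table. Growth factor receptors and ligands had a median of 2.80, with 10 of 14 at least 2-fold higher and 2 lower; NRG1 (12.77, on the outer curve) and AXL were the most extreme in the authors' deposited table. Adjusted over each list alone, 2 basal, 5 protease, 3 integrin and 2 growth factor genes passed 0.05, all higher, against 0 over all genes. With members lacking an adjusted p kept, the medians were 1.03 for basal, 1.38 for protease and 0.81 for growth factor genes. Of the genes fixed by name, CD44 stood at 2.65 and CD24, whose reads near-identical pseudogene copies can share, at -5.77 in the authors' deposited table.

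Cell cycle and proliferation genes had a median of 1.09, with 22 of 39 members at least 2-fold higher, 1 lower and 0 passing 0.05 adjusted over the list alone. CENPF stood at 2.65 and thymidylate synthase (TYMS) at 2.55 in the authors' deposited table. Hypoxia and glycolysis genes had a median of 1.29, with 13 of 24 at least 2-fold higher and 1 lower; lactate dehydrogenase B (LDHB), at 10.32 in the authors' deposited table, was the 1 member to pass 0.05 adjusted over the list alone. Antigen presentation genes had a median of 1.39 at percentile 99.5 of the random lists, with 5 of 8 at least 2-fold higher and TAP2 at 2.39 in the authors' deposited table. Cell cycle inhibitors and p53 targets had a median of -0.996 (percentile 0.24), 5 of 11 being at least 2-fold lower and 3 higher, with BTG2 at -9.20 in the authors' deposited table. Ribosomal protein genes had a median of -0.36 (percentile 0.49), and 35 of 38 lay within 2-fold. The antigen presentation, cell cycle inhibitor and ribosomal lists had 0 members passing 0.05 adjusted over the list alone, and they no longer stood outside the random lists when the mean replaced the median or when genes without an adjusted p were kept.

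In all, 16 of 31 lists with at least 5 measured members lay outside the central 95% of random lists, 10 above and 6 below. Lists of independently drawn genes would give 1.55. The fixed lists share members and may hold genes that vary together, so more than this can fall outside. The other 15 lay within, although with the mean in place of the median the reported TWIST1 targets (-1.50, percentile 0.63) and neuronal guidance (-1.59, percentile 1.59) lay below the random lists. Reported TWIST1 targets had a median of -0.09 over 14 members that went both ways, 4 at least 2-fold higher and 5 lower. Of all 5945 genes with an adjusted p, 1339 were higher and 858 lower by that measure. Breast stem cell markers had a median of 0.03 (of 6, 3 higher and 3 lower). TGF-beta and BMP signaling had 0.43 (of 16, 3 higher and 5 lower), Wnt signaling 0.26 (of 7, 1 and 1) and Notch signaling 0.64 (of 6, 2 and 1). A median near 0 over members that went both ways does not show that they were unchanged. The means of the stem cell, TGF-beta and Notch lists, -0.92, -0.84 and -0.73, differ in sign from their medians. SOX2 stood at -9.33, BMP7 at -13.35 on the outer curve and NOTCH3 at -9.08 in the authors' deposited table. Apoptosis regulators had a median of 0.58, cholesterol and fatty acid synthesis 0.66, unfolded protein and amino acid stress 0.69, and TWIST1's partners in the NuRD and polycomb complexes 0.30. The interferon response list had a median of -0.44, drug transport and detoxification -0.49, neuronal guidance and adhesion -0.65, and immediate early and heat shock genes -0.06. Reference genes stood at 0.39 and mitochondrially encoded genes at -0.24, with 6 of these 15 at least 2-fold lower. Adjusted over the list alone, members passed 0.05 in 5 of these 15 lists, against 0 over all genes.

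Among the markers of other cell types, only 3 of 13 endothelial and 1 of 11 immune genes with a fold had an adjusted p. All 3 endothelial markers with one, ROBO4 (9.34), ESAM (7.05) and ENG (5.86), and the 1 immune marker, CD68 (5.13), were higher in the MCF7-TWIST1 library in the authors' deposited table, as were 14 of the 18 mesenchymal structure genes by at least 2-fold. A marker low in MCF7-Ctrl may have an adjusted p only when high in MCF7-TWIST1, so the filter may set these directions. No fibroblast marker and no HOX gene had an adjusted p. Of 4 chemokines and inflammatory cytokines, 3 were at least 2-fold higher, among them CXCL8 (7.13) and IL11 (6.60), and 1 was lower, in the authors' deposited table. Over all 31 members in the table, 3 higher and 4 lower passed 0.05 adjusted over that list alone, against 0 over all genes. Of the endothelial list 2 passed, both higher, and of the immune, fibroblast, HOX and histone lists 0 passed. Of 2 replication-dependent histone genes, HIST2H2BE stood at -4.94 in the authors' deposited table and the other lay within 2-fold.

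The 12 highest genes in the authors' deposited table all lay on the outer curve and were MMP1, MSN, the actin-binding calponin CNN3, SRGN, ETS1, the serine synthesis enzyme PSAT1, CDCP1, the amino acid transaminase BCAT1, IFI16, COL8A1, RAB34 and ETV1. The 12 lowest were IGFBP5, XIST, TPD52L1, SYTL5, CACNG4, TFF1, GRHL2, TBX2, CDH1, FXYD3, PREX1 and MYH14, of which TFF1, CDH1 and PREX1 lay off the outer curve in the authors' deposited table. Their log2 folds ran from 13.19 for ETV1 to 16.18 for MMP1, and from -15.28 for IGFBP5 to -13.38 for MYH14, in the authors' deposited table.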

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

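Re-centring, the unadjusted p in each set of genes, the adjusted p of 0.1, protein-coding random lists, and leaving out the outer curve or the 17q23 and 20q13 regions were chosen after the data were seen. Against 1339 higher and 858 lower genes at 2-fold, a 1.5-fold threshold gave 2069 and 1408, and a 4-fold threshold 466 and 339. Keeping all genes gave 8191 and 12329, which turns the balance from 60.9% to 39.9% higher, and an unadjusted p under 0.05 over all genes, which changes threshold and filter together, gave 629 higher and 796 lower (44.1% higher). That threshold gave 152 and 120 (55.9% higher) among genes with an adjusted p, and 383 and 333 (53.5% higher) off the outer curve. Re-centring on the median of the same genes, which draws the 2 counts together by construction, moved the balance to 50.2% with 1086 and 1077 genes. Which direction is more frequent thus depends on the scaling and the filter, and the cause was not tested. Protein-coding genes, genes off the outer curve and genes outside the 2 regions kept both counts within 1.5 times. Counts of 0 genes at an adjusted p of 0.05 and at 0.01 stood against 75 at 0.1 in the authors' deposited table. Of 20520 genes at 2-fold in the authors' deposited table, the second table holds 8600. Re-centred, TWIST1 stood at 8.39. The number of lists outside the random lists was 16 in the main setting and 15 to 19 in the alternatives (19 of 37 lists when all genes were kept, and 15 of 27 without shared members), and no list compared moved to the opposite side. Without shared members, basal and mesenchymal-like line markers, both outside in the main setting, had too few members to be compared. Antigen presentation, cell cycle inhibitors and ribosomal proteins were lost with the mean and with all genes kept, and the last 2 also with random lists of all genes. Neuronal guidance and adhesion was newly outside with the mean, with all genes kept, without shared members and with protein-coding random lists, cholesterol and fatty acid synthesis with all genes kept and with random lists of all genes, and reported TWIST1 targets with the mean. With all genes kept, the medians moved from 7.27 to 2.77 for EMT transcription factors, from 5.57 to 1.89 for mesenchymal structure, from 4.25 to 1.03 for basal markers and from 2.80 to 0.81 for growth factor receptors. They became 1.38 for matrix proteases, 0.43 for antigen presentation, 6.59 for mesenchymal-like line markers and -5.47 for luminal keratins. Of the lists within, Notch signaling turned from 0.64 to -0.80 and breast stem cell markers from 0.03 to -0.87, while drug transport became -1.56 and neuronal guidance -1.74. Re-centred ribosomal proteins stood at -0.54, and the mean of unfolded protein genes was 1.33. None of the lists outside changed sign where compared. Re-centring, the only alternative run for single genes, shifts every gene alike and could not move a list among the random lists. Settings chosen beforehand but not run, since the tables hold no counts or levels, were TMM against size factors, library-size scaling, ERCC scaling, other pseudocounts, a mean of at least 5, the split by mean expression, edgeR and DESeq2 tests, and leaving out columns. No paired analysis was possible because each group has 1 sample and the tables hold no column per sample. Depth is unknown.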

Other observations

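The tests of chromosomal gains, of added RNA and of library depth were chosen after the results they bear on had been seen; the window and olfactory receptor tests were fixed before, although the outer curve was redefined between a first and the final run of the latter.

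Protein-coding genes outside the fixed lists and off the outer curve were ranked by fold, after their values were seen and with no test of any group among them. The highest were the transporter SLC43A3 at 12.05, the matrix-binding protein EDIL3 at 11.99, the receptor phosphatase PTPRM at 11.69, the transmembrane collagen COL13A1 at 11.22 and the cyclin CCND2 at 10.98 in the authors' deposited table. After PREX1, the lowest were the adenylyl cyclase ADCY1 at -12.44, SPTSSB at -11.30, the GDNF co-receptor GFRA1 at -11.29, FAM83H at -11.24 and the calcitonin receptor CALCR at -11.09 in the authors' deposited table.

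Grouped by symbol stem, 7 of 73 families of at least 8 genes lay outside the random lists, where independently drawn genes would give 3.65. The Rho exchange factors ARHGEF had a median of 1.98, with 6 of 8 at least 2-fold higher and 0 lower, and the kinesins KIF a median of 0.99 with 8 of 16 higher and 1 lower. The transcription factors ZBTB (-0.61) and the RPL genes outside the fixed list (-0.40) lay on the low side.

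Folds followed chromosomal position. The medians of 106 windows of 50 neighbouring genes had an SD of 0.552 log2, against at most 0.216 in 1000 shuffles, and among 4550 genes within 4-fold the SD was still 2.48 times the highest shuffle. The lowest window lay on chromosome 17 from 51.2 to 63.7 Mb (median -1.18, 98% of genes below the genome median) and the highest on chromosome 11 from 93.1 to 118.7 Mb (median 1.89). At 17q23 (chromosome 17, 59893046 to 62065282, GRCh38), 11 of 11 genes were at least 2-fold lower, among them RPS6KB1 (-3.64), PPM1D (-3.86) and APPBP2 (-3.79) in the authors' deposited table. At 20q13 (chromosome 20, 47501902 to 56392337), 11 of 27 genes were at least 2-fold lower and 24 of 27 lay below the genome median. PREX1 at -13.50, ZNF217 at -3.24 and ARFGEF2 at -0.29 were among these 24, while AURKA stood at 0.49, in the authors' deposited table. Some genes counted in the 2 regions overlap, such as RF02216 with ZFAS1 at 20q13 and AC005702.1 with RPS6KB1 at 17q23. The counts are therefore not of separate loci.

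The lower luminal and higher mesenchymal lists were weighed against 3 explanations. Regulation of genes alone, on the same chromosomes in both cell lines, is argued against by the window SD, 2.55 times the highest shuffle, although the shuffles do not model neighbouring genes regulated together. RNA of other cells added to unchanged MCF7 cells would lower alike only the MCF7 genes that those cells lack. Genes that both express would fall less, so the interquartile range of 5.68 log2 over the epithelial junction genes cannot decide it. Apart from scaling, though, no MCF7 gene could fall below the share of RNA that MCF7 cells still supplied. The median of -5.72 over the epithelial junction genes, with reference genes at 0.39, argues against a small or moderate addition. It leaves open an addition that made up nearly all of the RNA. It also stays open whether the MCF7-TWIST1 cells lack chromosomal gains the MCF7-Ctrl cells carry, as a diverged subline or another line would. The regions 17q23 and 20q13, both known gains of MCF7, lay -3.64 and -0.904 log2 from the genome median. The first was at percentile 0.07 of equally long runs of genes and the second at 9.29. These runs come from the same 2 libraries, where folds followed position, so the percentiles do not decide it. With 1 library per group, an effect of TWIST1 on these genes and any such difference in origin cannot be told apart, and both may contribute.

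More genes lay on the outer curve on the MCF7-Ctrl side (6755) than on the MCF7-TWIST1 side (3163). A deeper MCF7-Ctrl library is argued against as the whole cause: the lowest shared fold held 2941 genes on that side and 1565 on the other, 1.72 times (95% interval 1.62 to 1.83) what a size factor ratio of 1.09, read from the fold that 1077 genes share, the most shared off the outer curve, allows. More background reads from unexpressed genes in the MCF7-Ctrl library stay open: 75.3% of 97 olfactory receptor genes on the curve lay on its side (exact 95% interval 65.5 to 83.5), but so did 68.1% of all genes on the curve and 72.2% of protein-coding ones, and the bar of 60% set beforehand lay below these shares. Classes were not alike, since small nucleolar RNAs stood at 52.6% (42.1 to 63.0). The olfactory receptor interval includes the share of all genes on the curve.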
